A study of Rattus norvegicus with 24 samples.

How the data were processed

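Gene expression was measured in whole rat brain on 24 single-colour oligonucleotide arrays, 1 array per sample, with total RNA as the material. Per the labels, 12 arrays were controls and 4 groups of 3 arrays had repeated exposures of 90 min to 0.8% halothane or 1.0% isoflurane, with 2 exposures per day and 3 h of recovery between them, for 5 exposures over 2.5 days or 10 exposures over 5 days. The controls had 3 min of halothane before perfusion with ice-cold saline, and a sham exposure of the same length is not described for them. The labels do not say that replicates came from separate animals, so p-values measure the spread between these samples, which may be partly technical. The time between the last exposure and tissue collection is not given in the sources used here.

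The deposited table holds 1 intensity per probe set and array on a linear scale. The software that summarised the probes and scaled the arrays is not given in the sources used here, and neither are detection calls. The 2% trimmed mean of every array lay between 150.1 and 150.2, which is what a global scaling to a common target gives, and the deposited scaling was kept, as fixed for this case before the data were examined. Medians ranged from 53.5 to 64.9. No pair of arrays had identical values, and correlations between arrays ranged from 0.944 to 0.983. For arrays, the precision is limited by the number of arrays.

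Values under 16.5, the 25th percentile of the whole table, were set to 16.5 and log2 was taken, so that fold changes of dim genes are understated and a fold against a group at that floor depends on it. Where all arrays of a group lay at the floor, their spread became 0, which can lower the SE and p. Of 8799 probe sets, 59 spike-in and other control probe sets were left out, and probe sets above the floor on at least 3 arrays were kept, which left 7389. Of these, 6018 had 1 gene symbol in the platform annotation, 267 had several and 1104 were unnamed. Probe sets with several symbols were not named. Symbols were looked up through Entrez identifiers in a current rat gene table, where 6994 of 7018 single-gene probe sets were found, and 0 symbols changed. The probe sets with 1 symbol stand for 4206 genes.

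Comparisons were fitted with limma 3.58.1 in R 4.3.3 (lmFit, contrasts, eBayes with an intensity trend, two-sided) on all 24 arrays with 5 groups, which share an estimate of the spread. Adjusted p-values are limma's after Benjamini-Hochberg correction over the 7389 probe sets, and a change was called at an adjusted p under 0.05. Standard errors (SE) are those of the moderated fit, and intervals are 95% intervals. The 10 comparisons were each exposed group against control, the mean of the 4 exposed groups against control, the agents at 5 and at 10 exposures, 10 against 5 exposures of each agent, and the interaction of agent and exposure number.

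Gene lists were fixed before the data were examined, with 1 probe set per gene, the one with the highest mean signal. Of 33 lists, 32 had at least 3 measured genes, and the sex-linked list had 0. Lists were tested with limma's camera at a preset correlation of 0.01, corrected over the 32 lists within a comparison. Camera with an estimated correlation and fry served as alternatives, and with an estimated correlation 0 of the 32 lists were called in any comparison. For all 32 lists in each comparison of 1 exposed group with control, the list mean per array was also compared with an exact two-sided permutation test over all splits of the 15 arrays, corrected over the 32 lists, a test chosen after seeing the data, for which the smallest possible p is 0.0022.

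The named genes follow a rule fixed before the data were examined. In comparisons with control they are the 10 genes with the largest rise and the 10 with the largest fall among probe sets past the threshold with exactly 1 symbol, 1 probe set per gene by lowest p, and, where fewer than 5 passed, the 5 probe sets with the lowest p, which are then said not to have passed. In the other comparisons they are the 5 largest rises and the 5 largest falls, or the 3 lowest p where fewer than 3 passed. Up to 4 members with the lowest p were named from each list described, and 2 or 3 members of marker lists of other cell types were given as checks.

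Alternatives fixed before the data were examined were quantile normalization, median centring, floors at the 10th and the 40th percentile, no filter, a strict filter (above 58.9 on at least 12 arrays), no intensity trend, array weights, fits with only the groups of a comparison, controls 10 to 12 left out, the replicate number as a block, each array left out in turn and, for lists, the mean over all probe sets of a gene. Bacterial spike-in signals, from 9 probe sets, separated the arrays at a gap of 0.57 on the log2 scale into 9 arrays with a high level (5 controls and replicate 3 of every exposed group) and 15 with a low level (7 controls). The first principal component of the deviations from group means, with 22.5% of their variance, followed the same separation, except that control 2, with a low level, scored among the arrays with a high level. Fits with this spike-in level as a block, and fits on the low or the high arrays alone, were added after seeing the data, as were the list tests with each array left out in turn and other splits and shuffles of the arrays that keep the number of high and low arrays in each group. For the correlation of fold changes, unchanged groups were simulated with independent noise per probe set, and the covariance shared by equal replicate numbers was estimated from the deviations from group means, which leaves out what arrays of unequal numbers share. That estimate includes the spike-in level, which equal numbers share between the exposed groups.

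Replicate numbers were checked as possible pairs through the correlation of deviations from group means of arrays with the same number. For 10 exposures of halothane and of isoflurane these were 0.26, 0.22 and 0.47, and for 5 and 10 exposures of isoflurane 0.15, 0.30 and 0.46, so arrays with equal numbers deviated together. Arrays with unequal numbers were not compared in this way. In every exposed group replicate 3 alone had a high spike-in level, so these correlations do not show pairs, and the labels name none. The same held for 10 halothane and 5 isoflurane exposures (0.31, 0.29 and 0.52) and for 5 halothane and 10 isoflurane exposures (0.17, 0.11 and 0.26), which enter together only the interaction, the mean of the exposed groups and the correlations of fold changes. In the other pairs of groups at least 1 of the 3 correlations was under 0.1.

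The pipeline was tested on simulated data with independent noise per probe set. For halothane 10 vs control, 20.0% of 50 probe sets raised by 0.5 on the log2 scale were recovered among 7389, 76.0% of those raised by 1, 100% of those raised by 2 and 66.0% of those lowered by 1, with 8 false calls. A list of 27 genes raised by 0.3 was called by camera with 0 of the 31 other lists. Independent noise leaves out the correlation within real lists, estimated at 0.335 for ribosomal proteins. The simulation therefore does not give the rate of false list calls in the real data. Figures were drawn with matplotlib.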

Results

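The series measured whole rat brain after repeated exposure to a volatile anaesthetic, halothane or isoflurane, which are both halogenated inhaled agents. The groups were control (n = 12), 5 exposures to halothane (n = 3), 10 exposures to halothane (n = 3), 5 exposures to isoflurane (n = 3) and 10 exposures to isoflurane (n = 3). Halothane was given at 0.8% and isoflurane at 1.0%, so the agents were compared at equal numbers of exposures but at different concentrations. All 24 arrays had been scaled to nearly the same trimmed mean signal. The median 95% interval of a log2 fold change reached 0.41 to either side in a comparison of 3 arrays with the controls and 0.52 in a comparison of 3 with 3.

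**Figure D1:**
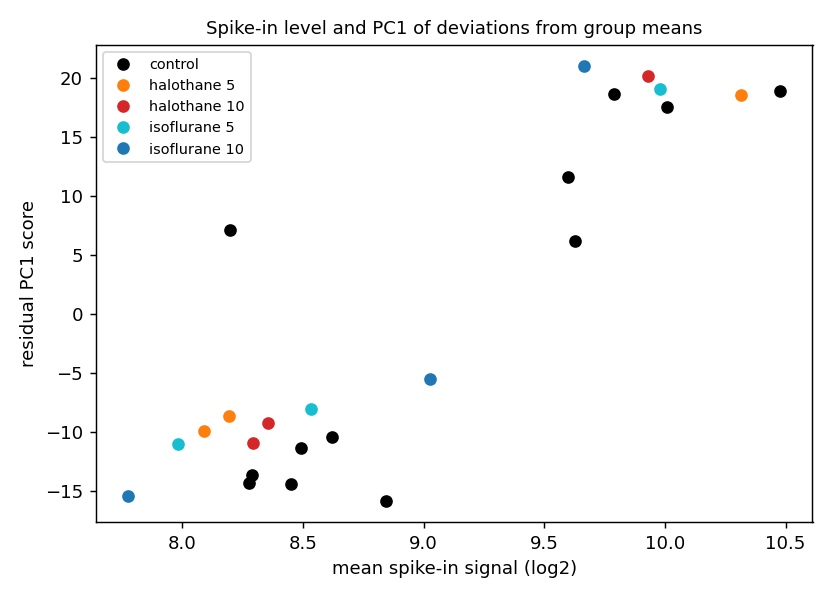
Mean log2 signal of the bacterial spike-in probe sets (x axis) against the score of each array on the first principal component of deviations from group means (y axis), coloured by group. The 9 arrays with a high spike-in level, which include 1 array of each exposed group, all have positive scores, as does control 2 among the arrays with a low level.

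The comparison of 5 halothane exposures with control asked which transcripts differ after the shorter course. Ugt2b35, a UDP-glucuronosyltransferase, was the only probe set that passed the threshold, of 7389. Its signal was 44.4 ± 25.6 (SD, n = 3) after 5 halothane exposures and 7.89 ± 3.55 (SD, n = 12) in control, where all 12 arrays lay at or below the floor of 16.5, and its log2 fold change against that floor was 1.28 ± 0.17 (SE, adjusted p = 0.00105). On the floored log2 scale the control SD was 0, against 0.76 after 5 halothane exposures. The SE and p therefore rest partly on values set to the floor. The call held in 9 of 13 other settings. These 9 count the fit on high spike-in arrays alone, which holds 1 array per exposed group and cannot show the spread within it. The settings that lost it include the floor at the 10th percentile (adjusted p = 0.0516) or the 40th (adjusted p = 0.968) and the low spike-in arrays (log2 fold change 1.48, adjusted p = 0.328). Without control 8 the count was 2, Sult1a1 then passing with a log2 fold change of 0.94. Sult1a1, a phenol sulfotransferase, had a signal of 93.9 ± 5.04 against 51.8 ± 10.7 in control, with all 3 arrays above the highest control array (88.1 against 77.6), but did not pass (log2 fold change 0.88, adjusted p = 0.142). The other lowest p-values, which did not pass either, belonged to the unnamed probe set rc_AA893040_at (-1.53, adjusted p = 0.496), to the glutamate dehydrogenase gene Glud1 (-0.50, adjusted p = 0.661) and to the kinase gene Cdc42bpb (-0.87, adjusted p = 1). At an unadjusted p under 0.05 there were 261 probe sets, where chance gives 369. Of the 32 gene lists, 0 were called by camera, the lowest adjusted p being 0.278, and 0.964 with an estimated correlation.

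After 10 halothane exposures 3 probe sets rose and 0 fell. Sult1a1 rose from 51.8 ± 10.7 (SD, n = 12) to 100.2 ± 5.92 (SD, n = 3), a log2 fold change of 0.98 ± 0.17 (SE, adjusted p = 0.0246), with all 3 arrays above every control. A second Sult1a1 probe set had a log2 fold change of 0.80 and did not pass (adjusted p = 0.0902). The unnamed probe set M33648_at had a signal of 70.4 ± 23.0 after 10 exposures and 8.04 ± 2.89 in control, where all arrays lay at or below the floor, and rose by 2.04 ± 0.25 against that floor (adjusted p = 0.00017). Its control SD on the floored log2 scale was 0, against 0.47 after 10 exposures, so its SE and p rest partly on values set to the floor. Phaf1 rose by 0.73 ± 0.13 (adjusted p = 0.0246), from signals near the floor, 15.6 ± 4.14 in control against 29.8 ± 8.51. Only 6 of 12 control arrays were above the floor. The call of Phaf1 held in 6 of 13 other settings, which include the fit on high spike-in arrays alone with 1 array per exposed group. Over these settings and the fits with 1 array left out, its log2 fold change ranged from 0.011 to 0.96. Vgf, which encodes a secreted neuropeptide precursor, had a signal of 269 ± 15.2 against 439 ± 61.9, a log2 fold change of -0.70 that just missed the threshold (adjusted p = 0.0557). At an unadjusted p under 0.05 there were 556 probe sets against 369 given by chance on average. Of 100 splits of the same arrays, the real grouping included, 15 reached that count, and 3 of 100 within the spike-in levels. Among low spike-in arrays the log2 fold changes were 0.90 for Sult1a1 (adjusted p = 0.189), 0.75 for Phaf1 (adjusted p = 0.189) and 2.05 for M33648_at (adjusted p = 0.0128), and with the spike-in level as a block 5 probe sets were called. Sult1a1 did not pass without halothane 10 replicate 1 (0.99), replicate 2 (0.93) or replicate 3 (1.01), nor Phaf1 without replicate 2 (0.52) or 3 (0.72), and the count was 6 without control 5, 5 without control 6, 6 without control 11, 1 with only the groups of the comparison and 33 with array weights.

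**Figure D2:**
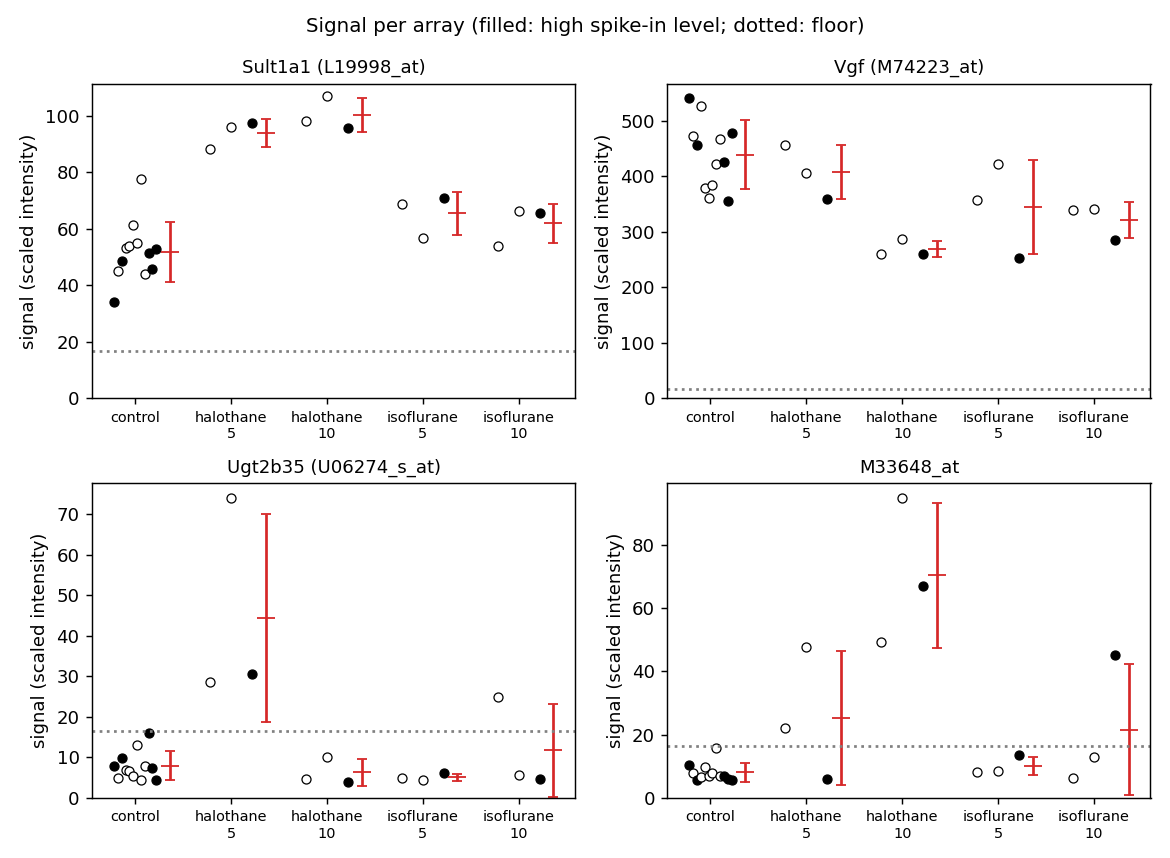
Signal (scaled intensity, y axis) of 4 probe sets on each array by group (x axis), with filled points for arrays with a high spike-in level, red marks for mean and SD, and a dotted line at the floor of 16.5. All 6 halothane arrays lie above the highest control array for Sult1a1, at 88.1 or more against 77.6.

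Of the 32 gene lists, 8 shifted after 10 halothane exposures by camera, 3 up and 5 down, and 0 with an estimated correlation; fry called 4. An exact permutation test of the list mean per array, corrected over all 32 lists, called 3 of them, the immediate early, glucocorticoid and blood lists. The immediate early genes, which respond quickly to neuronal activity, were lower (median log2 fold change -0.23, 18 of 21 measured members lower, adjusted p = 0.0135, and 0.145 with an estimated correlation). Of its members 0 passed over all probe sets, while adjusted over the list alone 1 rose and 3 fell: Junb (-0.62), Egr1 (-0.47) and Arc (-0.41) fell and Jun (0.53) rose. The median was -0.33 among low spike-in arrays. The list mean lay below every control on all 3 arrays (exact permutation p = 0.0022, the smallest possible, and 0.0352 after correction over the 32 lists). The glucocorticoid response list was higher (median 0.26, adjusted p = 0.00312, and 0.145 with an estimated correlation), with 10 of 11 members higher; 0 passed over all probe sets and, adjusted over the list alone, Sult1a1 rose (0.80). Errfi1 had a log2 fold change of 0.37, Sgk1 of 0.43 and Klf9 of 0.17. Its mean lay above every control on all 3 arrays (exact permutation p = 0.0022, adjusted 0.0352), and its median was 0.15 among low spike-in arrays. With each of the 24 arrays left out in turn both lists stayed called, and each was called in 8 of 10 other settings.

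The cholesterol synthesis list was lower after 10 halothane exposures (median -0.19, 16 of 18 lower, adjusted p = 0.00778, and 0.145 with an estimated correlation). Lss was at -0.50. The list also holds the fatty acid synthase gene Fasn (-0.51) and the regulators Insig1 (-0.38) and Srebf1 (-0.43), which are not enzymes of cholesterol synthesis. Past the threshold were 0 members, over all probe sets or adjusted over the list alone. Genes of monoamine and acetylcholine transmission were lower (median -0.21, 33 of 38 lower, adjusted p = 0.0031, and 0.34 with an estimated correlation), among them the receptor genes Chrm3 (-0.35), Adra1a (-0.61), Chrnb2 (-0.43) and Drd5 (-0.34), with 0 past the threshold adjusted over the list alone. Among low spike-in arrays the medians of these lists were -0.18 and -0.23. Ribosomal protein genes were higher (median 0.13, 33 of 37 higher, adjusted p = 4.24e-07, and 0.34 with an estimated correlation). Rpl14 was at 0.29, Rpl24 at 0.35, Rpl35a at 0.46 and Rpl26 at 0.34, with 0 members past the threshold adjusted over the list alone, and the list mean per array did not differ by more than the spread between arrays (exact permutation p = 0.215), with a median of 0.12 among low spike-in arrays. Without halothane 10 replicate 3 the ribosomal (median 0.091, adjusted p = 0.0504) and cholesterol lists (-0.15, adjusted p = 0.121) were not called. The cholesterol list was called in 8 of 10 other settings and the monoamine and ribosomal lists in 6 each.

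Markers of other cell types moved in the same group. Blood markers were lower (median -0.39, adjusted p = 0.00643, and 0.145 with an estimated correlation), with 0 members past the threshold over all probe sets and 3 adjusted over the list alone, the haemoglobin genes Hbb-b1 (-1.15) and Hbb (-0.91) and the erythroid haem synthesis gene Alas2 (-0.49), and the list mean was below every control on all 3 arrays (exact permutation p = 0.0044, adjusted 0.0469). The blood median was -0.47 among low spike-in arrays. With 1 array left out it ranged from -0.44 to -0.25, and the list stayed called in 24 of 24 fits. Choroid plexus and ependyma markers were higher (median 0.18, adjusted p = 0.0172, and 0.34 with an estimated correlation; exact permutation p = 0.033, adjusted 0.151), with Enpp2 at 0.47, Ttr at 0.42 and Sostdc1 at 0.49, and the median among low spike-in arrays was 0.016 (adjusted p = 0.572). Oligodendrocyte and myelin markers were lower (median -0.22, 9 of 9 lower, adjusted p = 0.0398, and 0.612 with an estimated correlation; exact permutation p = 0.171), with Mal at -0.25, Cnp at -0.27 and Mag at -0.31 and a median of -0.069 among low spike-in arrays (adjusted p = 0.584). For both of these lists 0 members passed adjusted over the list alone. Without halothane 10 replicate 3 neither was called. The choroid plexus median was then 0.056 (adjusted p = 0.492) and the myelin median -0.019 (adjusted p = 0.934), with the direction of the camera test turned for myelin. The myelin list was also not called without control 2, 6, 7 or 9. Blood markers were called in 7 of 10 other settings and the choroid plexus and myelin lists in 5 each.

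**Figure D3:**
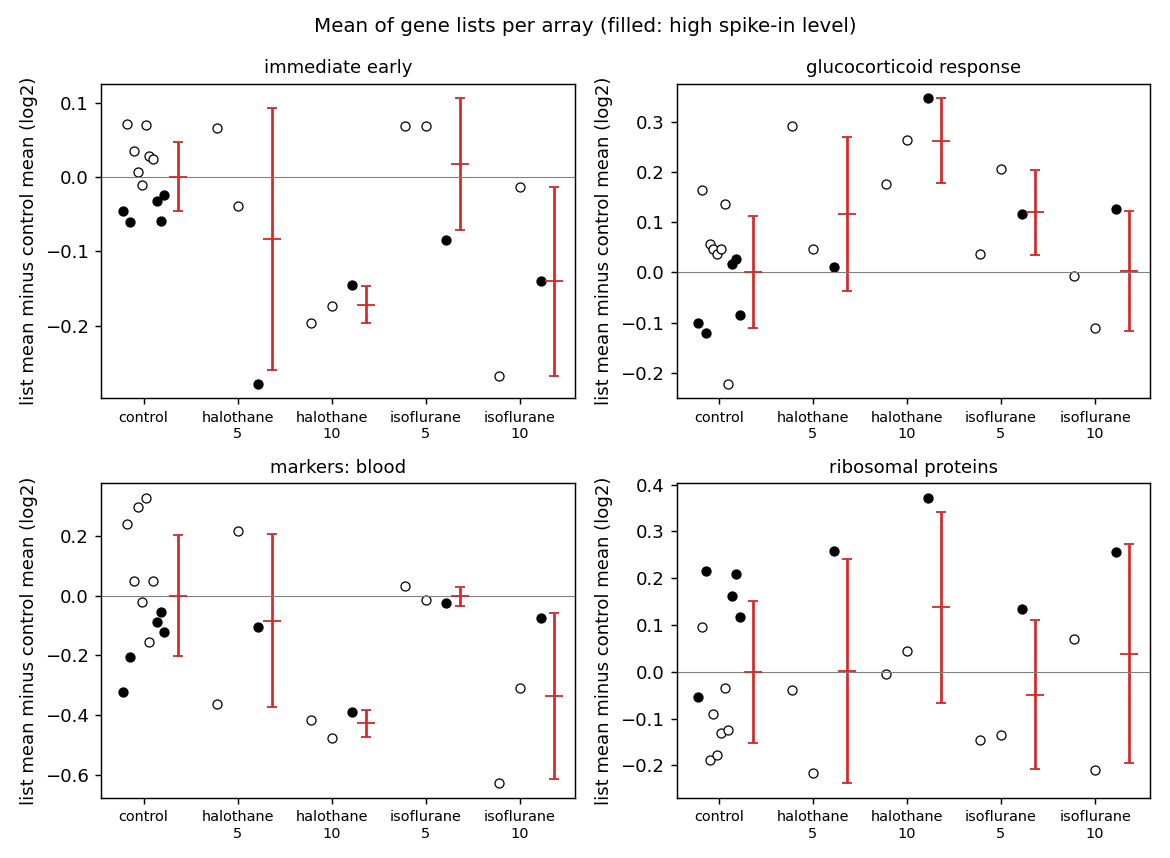
Mean log2 signal of 4 gene lists on each array minus the mean of the 12 controls (y axis) by group (x axis), with filled points for arrays with a high spike-in level and red marks for mean and SD. After 10 halothane exposures the immediate early and blood lists lie below every control, and the ribosomal protein list lies above every control on 1 of 3 arrays. The ribosomal list also lies above every control on 1 array after 5 halothane and 1 after 10 isoflurane exposures. Each of these arrays has a high spike-in level.

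After 5 isoflurane exposures limma called 0 probe sets, with 158 at an unadjusted p under 0.05 against 369 given by chance. The lowest p-values, none of which passed, belonged to the lysophosphatidic acid receptor gene Lpar2 (log2 fold change 0.82, adjusted p = 0.262), the olfactory marker gene Omp (0.38), the choline dehydrogenase gene Chdh (-1.09), the unnamed probe set rc_AA800942_at (0.72) and Smad9 (-1.04), all of them with an adjusted p of 1 except Lpar2. Lpar2 had a mean signal of 31.0 ± 4.59 (SD, n = 3) against 14.0 ± 5.12 in control, where 3 of 12 arrays were above the floor. It passed when only the groups of the comparison were fitted, with the spike-in level as a block (0.85, adjusted p = 0.0108), among low spike-in arrays (0.78, adjusted p = 0.000123) and without halothane 10 replicate 3, when the count was 1, over a range of adjusted p from 0.000123 to 1. Of the 32 lists, 0 were called, the lowest adjusted p being 0.0737, and 0.813 with an estimated correlation.

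After 10 isoflurane exposures limma called 0 probe sets, and 669 had an unadjusted p under 0.05 against 369 given by chance on average. Of 100 splits of the same arrays, the real grouping included, 17 reached that count, and 4 of 100 within the spike-in levels. Among the lowest p-values, none of which passed, the neuropeptide gene Gal had a log2 fold change of 0.92 (adjusted p = 0.0526), the transcription factor gene Gtf2a1 -1.17, the fatty acid hydroxylase gene Cyp4a1 -1.19, the lipid droplet gene Plin2 0.87 (adjusted p = 0.0597) and the axon guidance gene Slit1 -0.50 (adjusted p = 0.107). Gtf2a1 and Cyp4a1 had the same adjusted p as Gal. Gal lay at or below the floor on 11 of 12 control arrays and above it on 2 of 3 exposed arrays. Its log2 fold change was 0.75 without isoflurane 10 replicate 2 (adjusted p = 0.183). Gal is also a member of the pituitary marker list, which was not called (adjusted p = 0.554, median -0.0098, mean 0.18). Among its other members Pomc was at 0.89 (adjusted p = 0.631), with a mean signal of 90.5 against 38.6 in control, and Gh1 at 0.22 (adjusted p = 0.926), with 78.4 against 47.3. The mean of that list was 6.42 on isoflurane 10 replicate 2 and 5.13 and 5.42 on the other arrays, an SD of 0.679 against 0.176 in control. A second Cyp4a1 probe set went the other way (0.35, adjusted p = 0.86). The count was 3 without control 3, 5 without isoflurane 10 replicate 1, 2 without isoflurane 10 replicate 3, 4 with median centring, 3 with the spike-in level as a block and 4 among low spike-in arrays.

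By camera 4 gene lists were lower after 10 isoflurane exposures, and 0 with an estimated correlation or by the exact permutation test corrected over the 32 lists (lowest adjusted p = 0.399). The immediate early genes had a median of -0.16, with 16 of 21 lower (adjusted p = 0.0393, and 0.332 with an estimated correlation; exact permutation p = 0.0132), and Egr1 (-0.51), Junb (-0.50), Fos (-0.41) and Nptx2 (-0.36) had the lowest p-values, with 0 past the threshold adjusted over the list alone. Heat shock and chaperone genes had a median of -0.15 (adjusted p = 0.016, and 0.408 with an estimated correlation; exact permutation p = 0.0264). Of its 23 members 0 passed over all probe sets and 4 fell adjusted over the list alone, the small heat shock protein gene Hspb1 (-0.52), Dnajb1 (-0.37), Hsp90b1 (-0.31) and Hsf1 (-0.40). Neurotrophin and growth factor genes had a median of -0.21 (adjusted p = 0.0209, and 0.332 with an estimated correlation; exact permutation p = 0.0571), and adjusted over the list alone Ngfr (-0.48) and Vgf (-0.44) fell, while 0 passed over all probe sets. Monoamine and acetylcholine genes had a median of -0.17 (adjusted p = 0.0417, and 0.691 with an estimated correlation; exact permutation p = 0.222), with Chrnb2 at -0.50, Htr3a at -0.32, Adra1d at -0.43 and Maob at 0.28, and 0 members passed adjusted over the list alone. Among low spike-in arrays the medians of the 4 lists, in this order, were -0.22, -0.11, -0.27 and -0.083. The monoamine list was not called there (adjusted p = 0.505), while the other 3 were. Leaving out isoflurane 10 replicate 3 ended the call of all 4 lists, with medians of -0.16, -0.093, -0.12 and -0.0097. Leaving out replicate 1 ended it for the immediate early (-0.051), neurotrophin (-0.095) and monoamine lists (-0.060), and leaving out replicate 2 for the immediate early list (-0.24). The immediate early list was also lost without control 2 or 8, and the monoamine list without control 4, 6, 8, 9 or 11. The monoamine list was called in 4 of 10 other settings and the others in 5 each. The mean of the monoamine list lay above every control on 1 exposed array, replicate 2, and below every control on 2 (SD 0.326 against 0.118 in control). With 1 array left out its median ranged from -0.34 to -0.0097. Blood markers were not called on all arrays (median -0.12, adjusted p = 0.0706), with Hbb at -0.95 and Hbb-b1 at -0.86, but were called among low spike-in arrays (median -0.41, adjusted p = 0.00308).

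Over the 4 exposed groups, limma called 0 probe sets, and 624 had an unadjusted p under 0.05 against 369 given by chance on average. Of 100 splits of the same arrays, the real grouping included, 14 reached that count, and 5 of 100 within the spike-in levels. Sult1a1 came closest (log2 fold change 0.62 ± 0.11, SE, adjusted p = 0.0654), followed by M33648_at (0.79), Alas1, the first enzyme of haem synthesis (0.51), Vgf (-0.40) and the receptor gene Igf2r (0.97). A second Alas1 probe set was at 0.023. Among low spike-in arrays Sult1a1 was at 0.49 (adjusted p = 0.244). Its signal on the isoflurane arrays, 54 to 70.8, lay within the control range of 33.9 to 77.6. The top of that range was control 8 alone, the next control being at 61.4. The isoflurane means, 65.4 after 5 and 61.9 after 10 exposures, lay above the control mean of 51.8. On the second Sult1a1 probe set the highest signal was 174.2 after 5 and 197.1 after 10 isoflurane exposures, against 184.9 in control. The count was 1 without control 8, 1 without halothane 5 replicate 3 and 3 without isoflurane 10 replicate 1.

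By camera 7 lists were called in all exposed groups together, and 0 with an estimated correlation. Among low spike-in arrays 2 of these 7 were called, apoptosis (adjusted p = 0.0237) and blood (adjusted p = 0.0057), as was the neurotrophin list (adjusted p = 0.0237). The adjusted p there missed the threshold for the immediate early (0.21), heat shock (0.348), glucocorticoid (0.386), ribosomal (0.267) and monoamine (0.153) lists. Immediate early genes had a median of -0.13 (adjusted p = 0.0449), with Egr1 at -0.33, Egr4 at -0.30 and Jun at 0.30. Heat shock genes had a median of -0.073 (adjusted p = 0.0462), with Hspb1 at -0.28, and the apoptosis list of -0.15 (adjusted p = 0.0449), with Casp1 at -0.22 and Bcl2l11 at -0.24. In the apoptosis list 14 of 16 members were lower and 2 higher. At an unadjusted p under 0.05 were 3 of the lower and 1 of the higher. Monoamine and acetylcholine genes had a median of -0.10 (adjusted p = 0.0165), with Chrnb2 at -0.45, and blood markers of -0.11 (adjusted p = 0.0449), with Hbb at -0.60. Glucocorticoid response genes had a median of 0.11 (adjusted p = 0.0462) and ribosomal protein genes of 0.053 (adjusted p = 0.0449). With an estimated correlation the adjusted p was 0.366 for the immediate early, apoptosis, blood and glucocorticoid lists, 0.584 for the heat shock and monoamine lists and 0.835 for ribosomal proteins. Adjusted over the list alone, Hspb1, Chrnb2, Hbb, Hbb-b1 and Alas2 fell and Sult1a1 rose, while 0 members passed over all probe sets. In the 10 other settings the call held in 1 for immediate early, 3 for heat shock, 5 for apoptosis, 4 for monoamine, 3 for blood, 0 for glucocorticoid and 2 for ribosomal genes. With the spike-in level as a block the glucocorticoid list just missed the threshold (adjusted p = 0.0518). With the replicate number as a block, on fewer controls, 0 lists were called. With each of the 24 arrays left out in turn, the call was kept 12 times for immediate early, 11 for heat shock, 20 for apoptosis, 22 for monoamine, 13 for blood, 7 for glucocorticoid and 12 for ribosomal genes. The median then ranged from -0.15 to -0.055 for immediate early, from -0.10 to -0.036 for heat shock and from 0.023 to 0.076 for ribosomal genes. Without halothane 5 replicate 3, or without isoflurane 10 replicate 1, 0 of these 7 lists were called.

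At 5 exposures the agents differed in 1 probe set. Ugt2b35 was higher after halothane than after isoflurane by 1.28 ± 0.22 (SE, adjusted p = 0.0401), with all isoflurane arrays at or below the floor, and among low spike-in arrays by 1.48 (adjusted p = 0.947). On the floored log2 scale the SD was 0 after isoflurane and 0.76 after halothane, so the SE rests partly on values set to the floor. The call held in 5 of 13 other settings, counting the fit on high spike-in arrays alone. That fit holds 1 array per exposed group and cannot show a difference between the agents. The settings that lost it include the floor at the 10th or the 40th percentile, no filter, no intensity trend, a fit of only these groups and the fit without controls 10 to 12. It also did not pass without any 1 of the 12 controls, of the 3 arrays after 10 halothane exposures or of the 3 after 5 isoflurane exposures, each at 1.28, with a count of 0, and the count was 2 without halothane 5 replicate 1. The choroid plexus transcript Ttr, which encodes transthyretin, was at -1.01 (95% interval -1.52 to -0.50, adjusted p = 1) and the unnamed rc_AA893040_at at -1.76 (adjusted p = 1). Choroid plexus markers were lower after halothane (median -0.29, 11 of 13 lower, adjusted p = 0.00891, and 0.659 with an estimated correlation), with Sostdc1 at -0.67, Aqp1 at -0.49 and a median of -0.083 among low spike-in arrays (adjusted p = 0.509); adjusted over the list alone Ttr fell, and 0 members passed over all probe sets. The choroid plexus list was not called without halothane 5 replicate 3 (-0.18, adjusted p = 0.0705) or isoflurane 5 replicate 3 (-0.18, adjusted p = 0.33). Its mean was 7.02 on that halothane array against 7.26 and 7.19 on the other 2, and 7.66 on that isoflurane array against 7.36 and 7.29. The same halothane array was low in brain region markers (6.85 against 7.84 and 7.92, SD 0.593 against 0.122 in control). It was low in neuropeptides as well (6.69 against 7.40 and 7.41, SD 0.413 against 0.0747). Neither of these lists was called between the agents (adjusted p = 0.694 and 0.936). Heat shock genes were higher after halothane (median 0.12, adjusted p = 0.0445, and 0.793 with an estimated correlation), with Fkbp4 at 0.38, Cryab at 0.50, a median of 0.046 among low spike-in arrays (adjusted p = 0.482) and 0 members past the threshold adjusted over the list alone. That list was not called without control 6, 10 or 11, any 1 of the 3 halothane 5 arrays, or isoflurane 5 replicate 2 or 3 (0.089, adjusted p = 0.33, without replicate 3). Heat shock genes were called in 3 of 10 other settings and the choroid plexus list in 6. Sult1a1 differed by 0.53 (95% interval 0.071 to 0.98, adjusted p = 1). For 79.1% of probe sets the 95% interval excluded a 2-fold difference. This share includes dim probe sets, whose differences and spreads are understated by the floor.

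At 10 exposures limma called 0 probe sets between the agents, with 230 at an unadjusted p under 0.05 against 369 given by chance. The 95% interval excluded a 2-fold difference for 79.3% of probe sets, again with dim probe sets whose differences and spreads the floor understates. M33648_at was higher after halothane (log2 difference 1.56, adjusted p = 0.36), Gal was at -0.92 and the zinc finger gene Zfp64 at -1.07, and Sult1a1 at 0.70 (95% interval 0.24 to 1.16), none of which passed. The count was 1 without halothane 5 replicate 2, halothane 10 replicate 2, isoflurane 10 replicate 1 or isoflurane 10 replicate 3. Glucocorticoid response genes were higher after halothane (median 0.25, adjusted p = 0.00694, and 0.213 with an estimated correlation), with Errfi1 at 0.32 and Nfkbia at 0.55. Ribosomal protein genes were higher (median 0.095, adjusted p = 0.00171, and 0.601 with an estimated correlation), with Rpl27a at 0.23 and Rpl22 at 0.26. Ubiquitin and proteasome genes were higher (median 0.10, adjusted p = 0.00694, and 0.515 with an estimated correlation), with Psme2 at 0.87 and Psma5 at 0.23. Cholesterol synthesis genes were lower after halothane (median -0.16, adjusted p = 0.0499, and 0.515 with an estimated correlation), with Sqle at -0.27 and Msmo1 at -0.26. In these lists 0 members passed over all probe sets or adjusted over the list alone. The medians among low spike-in arrays were 0.15, 0.053, 0.16 and -0.18 in this order, and the cholesterol list was not called there (adjusted p = 0.186). Without halothane 10 replicate 3 the glucocorticoid (0.16), ribosomal (-0.027) and cholesterol lists (-0.14) were not called. Without isoflurane 10 replicate 2 0 of the 4 were called, with medians of 0.26, -0.0097, 0.069 and -0.15 in the same order. The ubiquitin list was also lost without halothane 10 replicate 1 (0.052), and the cholesterol list stayed called in 10 of 24 fits with 1 array left out. Over 10 other settings the cholesterol list was called in 5 and the others in 7 each.

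Between 5 and 10 halothane exposures 1 probe set differed. Ugt2b35 fell by 1.28 ± 0.22 (SE, adjusted p = 0.0401), down to the floor on all 3 arrays. Their SD on the floored log2 scale was 0, so the SE rests partly on values set to the floor. The call held in 4 of 13 other settings, counting the fit on high spike-in arrays alone, which holds 1 array per exposed group. The settings that lost it include median centring, the floor at the 10th or the 40th percentile, no filter and no intensity trend. They also include a fit of only these groups, the fit without controls 10 to 12 and the low spike-in arrays (-1.48). It did not pass without any 1 of the 12 controls, of the 3 arrays after 10 halothane exposures or of the 3 after 5 isoflurane exposures, each at -1.28. The count was then 0, except for 1 other probe set without halothane 10 replicate 1 or 2, and it was 2 without halothane 5 replicate 1 or 2 or isoflurane 10 replicate 3. The cytokine gene Il33 was at 1.34 (adjusted p = 0.176) and Phaf1 at 0.74 (adjusted p = 0.303). Choroid plexus markers were higher after 10 exposures (median 0.21, adjusted p = 0.000342, and 0.261 with an estimated correlation), and adjusted over the list alone Ttr rose (0.99), while 0 members passed over all probe sets. Ribosomal protein genes were higher (median 0.11, adjusted p = 6.88e-05, and 0.592 with an estimated correlation), with Rpl14 at 0.39. Cholesterol synthesis genes were lower (median -0.22, adjusted p = 0.0198, and 0.358 with an estimated correlation), with Dhcr7 at -0.37, and heat shock genes were lower (median -0.15, adjusted p = 0.0261, and 0.453 with an estimated correlation), with Hspb1 at -0.25. In these 3 lists 0 members passed adjusted over the list alone. Among low spike-in arrays the medians of the 4 lists, in this order, were 0.074, 0.078, -0.18 and -0.14. The choroid plexus (adjusted p = 0.157) and heat shock lists (adjusted p = 0.347) were not called there. Without halothane 10 replicate 3 0 of the 4 were called (0.12, 0.017, -0.16 and -0.090). Without halothane 5 replicate 2 the ribosomal (0.058), cholesterol (-0.14) and heat shock lists (-0.11) were lost, and without halothane 5 replicate 1 the heat shock list (-0.12). In the 10 other settings the heat shock list was called in 5, the choroid plexus list in 6 and the other 2 in 7 each.

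Between 5 and 10 isoflurane exposures limma called 0 probe sets, with 222 at an unadjusted p under 0.05. Cyp4a1 was at -1.34, Lpar2 at -0.90 and Gal at 0.92, each with an adjusted p of 0.506, and the count was 2 without isoflurane 10 replicate 1 and 1 among low spike-in arrays. Neurotrophin and growth factor genes were lower after 10 exposures (median -0.20, 20 of 27 lower, adjusted p = 0.0457, and 0.346 with an estimated correlation), with Igf1r at -0.42, Ngfr at -0.35 and 0 members past the threshold adjusted over the list alone. The median was -0.22 among low spike-in arrays, and with the replicate number as a block 2 lists were called. The neurotrophin list was not called without control 3 or 7, isoflurane 5 replicate 2 (-0.11), isoflurane 10 replicate 1 (-0.14) or isoflurane 10 replicate 3 (-0.16), and it was called in 5 of 10 other settings.

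For the interaction of agent and exposure number limma called 0 probe sets, with 148 at an unadjusted p under 0.05. Ugt2b35 had a difference of log2 fold changes of -1.48 (adjusted p = 0.57), the elongation factor gene Supt5h of 3.24 (SE 0.92, adjusted p = 1) and Lpar2 of 0.98 (adjusted p = 1), and the count was 1 without isoflurane 10 replicate 1. Supt5h was above the floor on 0 arrays after 5 halothane exposures and on 1 after 10 isoflurane exposures, so its value depends on the floor. Choroid plexus markers had a positive interaction (median 0.44, adjusted p = 0.0038, and 0.479 with an estimated correlation), with Ttr at 1.02, Igf2 at 0.47, a median of 0.18 among low spike-in arrays (adjusted p = 0.783) and 0 members past the threshold adjusted over the list alone. The list was not called without halothane 10 replicate 3 (0.35), isoflurane 5 replicate 3 (0.32) or isoflurane 10 replicate 1 (0.30), and it was called in 6 of 10 other settings.

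The 4 comparisons with control share their 12 control arrays, so their fold changes correlate without any effect. The highest correlation was between 10 halothane and 10 isoflurane exposures, at 0.504 across probe sets, which are not independent replicates, against 0.201 in simulated unchanged groups with the same controls and a mean of 0.223 (highest 0.457) over 100 shuffles of the arrays between groups within the spike-in levels. The covariance was 0.0357 against a simulated 0.0125. The simulation leaves out what equal replicate numbers share, and the shuffles keep of it only the spike-in level. This share was estimated at 0.017 of the covariance between these groups, but the estimate includes the spike-in level. Between 5 halothane and 5 isoflurane exposures it was 0.0101, above the whole covariance of 0.00861, so it does not size the share. With the controls split into separate sets of 6 the correlation was 0.291 and the covariance 0.0239. Among probe sets with an unadjusted p under 0.05 in both, 84 were higher and 82 lower in both, against 15.4 and 14.8 in simulated unchanged groups, 8.27 and 8.87 on average in the shuffles (highest 43 and 28) and 11.2 and 14.0 for independent lists, which leave out the shared controls. The counts hold what equal replicate numbers share as well, and 0 probe sets were called in both. Between 5 halothane and 5 isoflurane exposures the correlation was 0.184 against a simulated 0.201, and -0.051 with separate sets of 6 controls.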

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

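Of the tests below, the fits and splits by spike-in level, the permutation of list means, the list tests with 1 array left out and the comparison of Sult1a1 between the agents were chosen only after the data were seen, and the limits for reading the choroid plexus and batch tests were narrowed after their values were seen, which weakened the readings.

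Choroid plexus markers differed between agents at 5 exposures (median -0.287), between 10 and 5 halothane exposures (0.211) and in the interaction (0.435), by tests of the differences themselves, but not with an estimated correlation (adjusted p = 0.659, 0.261 and 0.479). The call at 5 exposures was lost without halothane 5 replicate 3 (adjusted p = 0.0705), whose brain region markers (6.85 against 7.84 and 7.92) and neuropeptides (6.69 against 7.40 and 7.41) were low as well, or without isoflurane 5 replicate 3 (adjusted p = 0.33). Unequal sampling of choroid plexus or other tissue may account for this, but over the 12 controls the median Spearman rho of Ttr with the other markers was -0.0035, at percentile 49.8 of 10000 matched lists, too near the limit of 50 to decide. A hybridisation batch may also contribute, since the median at 5 exposures was -0.083 among low spike-in arrays, with an SE of 0.118 for the list mean there, but an equal offset between spike-in levels cancels in these differences, since each exposed group holds 1 high array. Neither can be told apart from an effect of the agents with 2 low arrays per exposed group.

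Ribosomal protein genes were higher after 10 halothane exposures than in control (median 0.13), than after 10 isoflurane exposures (0.0949) and than after 5 halothane exposures (0.11), but with an estimated correlation none of these passed (adjusted p = 0.34, 0.601 and 0.592). A signal-dependent difference between arrays is argued against, since lists matched on mean signal had a median of -0.028 and the list lay at percentile 100. An equal offset between spike-in levels could not be tested as the whole cause, since it largely cancels in this comparison by design. Of the controls 5 were high and 7 low, and after 10 halothane exposures replicate 3 alone was high. The shift of the list mean was 0.16 (SE 0.0655) with the spike-in level as a block and 0.14 without it. The design keeps this difference small, so no conclusion is drawn from it. The list was still called by camera with the block (adjusted p = 5.11e-10) and among low spike-in arrays (median 0.12, adjusted p = 0.000132), but the SE of the list mean among low arrays, 0.0859, does not exclude a batch that acts unequally on the groups. An effect of halothane stays open, the exact permutation p of the list mean was 0.215, and without halothane 10 replicate 3, an array with a high spike-in level, the medians were 0.091, -0.027 and 0.017 and 0 of the 3 were called.

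Sult1a1 was higher in the exposed groups than in control by a log2 fold change of 0.62, which did not pass over all probe sets (adjusted p = 0.0654). Its signal on the isoflurane arrays, 54 to 70.8, lay within the control range of 33.9 to 77.6, and on the halothane arrays, at 88.1 or more, above it. The top of that range was control 8 alone, the next control being at 61.4. The isoflurane means, 65.4 after 5 and 61.9 after 10 exposures, lay above the control mean of 51.8. Among low spike-in arrays its log2 fold change stayed above 0, at 0.49 with an SE of 0.131, but did not pass either (adjusted p = 0.244). An equal offset between spike-in levels largely cancels in this comparison by design. Sult1a1 was also singled out by a fit that includes these low arrays. No conclusion about a batch is therefore drawn. A response to handling that is equal for both agents is argued against as the whole cause, since Sult1a1 was higher after halothane than after isoflurane by 0.61 (SE 0.156) over 5 and 10 exposures on the same schedule, although 0.61 did not pass over all probe sets (adjusted p = 1) and halothane values helped to single out Sult1a1. A glucocorticoid response could account for part of it, since the rest of that list had a median of 0.10 (camera p = 0.0817). After 5 exposures the mean of the whole list was 0.116 above control for halothane and 0.120 for isoflurane (exact permutation p = 0.158 and 0.106). All 3 arrays of both groups lay above the control mean. After 10 isoflurane exposures, however, the mean was only 0.0029 above control. The agents differed in that list there (median 0.252, adjusted p = 0.00694, and 0.213 with an estimated correlation). An effect of the agents, which were given at different concentrations, stays open.

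The remaining differences between groups that passed a test of the difference itself are given as values. Ugt2b35 differed by 1.28 between agents at 5 exposures and by -1.28 between 10 and 5 halothane exposures, and these calls held in only 5 and 4 of 13 other settings. Both numbers count the fit on high spike-in arrays alone, which holds 1 array per exposed group. With an estimated correlation 0 of the lists below were called, and the adjusted p there is given in parentheses. Heat shock genes had a median difference of 0.125 (0.793) between agents at 5 exposures and of -0.15 (0.453) between 10 and 5 halothane exposures. Between agents at 10 exposures the medians were 0.252 (0.213) for glucocorticoid response, -0.165 (0.515) for cholesterol synthesis and 0.1 (0.515) for ubiquitin and proteasome genes. Cholesterol synthesis genes had a median of -0.217 (0.358) between 10 and 5 halothane exposures, and neurotrophin genes of -0.199 (0.346) between 10 and 5 isoflurane exposures.

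Splits of the same arrays were refitted, 100 for each comparison with control and the interaction. Here and below the real grouping is 1 of the splits and is counted among those that reach its count. Over all splits chance was not excluded in any of these comparisons. Where the real count was 0, here and below, every split reaches it, so only the unadjusted count is informative there. For 5 halothane exposures 34 splits gave at least the real count of 1, the highest other being 89, and 67 gave at least the 261 at an unadjusted p under 0.05, the highest other being 1130. For 10 halothane exposures 9 splits reached the real 3 (highest other 8) and 15 the 556 (highest other 1060). For 5 isoflurane exposures 100 reached 0 (highest other 11) and 90 the 158 (highest other 1109). For 10 isoflurane exposures 100 reached 0 (highest other 34) and 17 the 669 (highest other 1043). For all exposed groups 100 reached 0 (highest other 11) and 14 the 624 (highest other 1130). For the interaction 100 reached 0 (highest other 3) and 92 the 148 (highest other 1151).

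Such splits mix the spike-in levels, while each exposed group holds 1 high and 2 low arrays. For each of the 4 single groups the split with most unadjusted calls set apart 3 arrays with a high spike-in level, controls 3, 10 and 11 or, for 5 halothane exposures, controls 1 and 11 and halothane 5 replicate 3. The many calls of such splits point to this structure of the samples.

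Of 100 splits that keep the number of high and low arrays in each group, the numbers that reached the real counts are given with the highest other count in parentheses. For 5 halothane exposures 35 reached 1 (highest other 4) and 61 the 261 unadjusted (541). For 10 halothane exposures 7 reached 3 (20) and 3 the 556 (745). For 5 isoflurane exposures 100 reached 0 (5) and 84 the 158 (677). For 10 isoflurane exposures 100 reached 0 (11) and 4 the 669 (701). For all exposed groups 100 reached 0 (14) and 5 the 624 (1008). For the interaction 100 reached 0 (2) and 86 the 148 (694). With the spike-in level also as a block, 36 reached 1 (6) and 60 the 342 (764) for 5 halothane exposures. For 10 halothane exposures 4 reached 5 (42) and 3 the 748 (990). After 5 isoflurane exposures 41 reached 1 (14) and 85 the 201 (924). After 10 isoflurane exposures 14 reached 3 (34) and 5 the 860 (982). All exposed groups had 100 at 0 or more (19) and 3 at 825 (1141), and the interaction 100 at 0 or more (1) and 84 at 196 (920). So within the spike-in levels fewer than 5 of 100 splits reached the unadjusted count of 10 halothane exposures in both fits and that of 10 isoflurane exposures without the block. With the block the same held for the adjusted count of 10 halothane exposures and the unadjusted count of all exposed groups. These splits do not keep what arrays with equal replicate numbers share between exposed groups, and no correction was made for the number of counts tested. They are therefore a thin basis, and chance is not excluded for any count.

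The comparisons of 3 with 3 arrays have only 10 splits, the real grouping included, too few for a share under 0.05. Between agents at 5 exposures 1 split, the real grouping, reached the real 1 (highest other 0) and 7 the 220 unadjusted (highest other 449). Between agents at 10 exposures 10 reached 0 (highest other 1) and 8 the 230 (highest other 897). Between 10 and 5 halothane exposures 1, again the real grouping, reached 1 (highest other 0) and 7 the 278 (highest other 701). Between 10 and 5 isoflurane exposures 10 reached 0 (highest other 4) and 8 the 222 (highest other 831).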

How the results depend on the processing

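The fits by spike-in level were chosen only after the data were seen. Here a single group named alone, or all exposed groups, stands for its comparison with control. The numbers of values below cover all 10 comparisons. Over the alternatives other than leaving out 1 array, 45 values of named probe sets passed where they had not, 33 no longer passed and the others kept their direction and side of the threshold. With 1 array left out 25 passed, 41 no longer passed and 894 kept theirs. Of the values of called lists 161 stayed called, 148 did not pass and 1 changed sign, that of the list ribosomal proteins, all exposed vs control, whose median of 0.053 became -0.00611 under the replicate block. The list tests with 1 array left out were also chosen after the data were seen. There 604 values of called lists stayed called, 138 did not pass and 2 turned in direction by camera. These were the myelin list for halothane 10, over a range of medians from -0.3687 to -0.0191 (without halothane 10 replicate 3), and the ribosomal list between agents at 10 exposures, over a range from -0.02711 to 0.1827 (turned without isoflurane 10 replicate 2, at -0.00971). The cause of a change was not tested, except where fewer arrays or probe sets entered. Signal over background limits Ugt2b35, M33648_at and Gal, whose controls lay at the floor, apart from 1 array for Gal. It also limits Phaf1, Lpar2 and Omp, with 6, 3 and 3 of 12 control arrays above the floor, and Supt5h in the interaction.

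The counts of probe sets were 1 for halothane 5, 3 for halothane 10, 0 for isoflurane 5, 0 for isoflurane 10, 0 for all exposed, 1 for agents at 5 exposures, 0 for agents at 10 exposures, 1 for halothane 10 vs 5, 0 for isoflurane 10 vs 5, 0 for the interaction. With quantile normalization they were 2 for halothane 5, 6 for halothane 10, 1 for all exposed. With median centring they were 2 for halothane 5, 5 for halothane 10, 4 for isoflurane 10, 1 for all exposed, 0 for halothane 10 vs 5. With the floor at the 10th percentile they were 0 for halothane 5, agents at 5 exposures and halothane 10 vs 5. With the floor at the 40th percentile they were 5 for halothane 10, 1 for isoflurane 10 and all exposed, 0 for agents at 5 exposures and halothane 10 vs 5. With no filter they were 1 for all exposed, 0 for agents at 5 exposures and halothane 10 vs 5. With the strict filter, which tested 4392 probe sets, they were 0 for halothane 5, agents at 5 exposures and halothane 10 vs 5, 1 for halothane 10 and all exposed, 2 for isoflurane 10. With no intensity trend they were 2 for halothane 5, 5 for halothane 10, 4 for isoflurane 10, 1 for all exposed, 0 for agents at 5 exposures and halothane 10 vs 5. With array weights they were 33 for halothane 10, 1 for isoflurane 5, 2 for halothane 10 vs 5. With only the groups of the comparison they were 1 for halothane 10 and isoflurane 5, 0 for agents at 5 exposures and halothane 10 vs 5. Without controls 10 to 12 they were 1 for halothane 10 and isoflurane 10, 0 for agents at 5 exposures and halothane 10 vs 5. With the replicate block, on fewer controls, they were 0 for halothane 5, agents at 5 exposures and halothane 10 vs 5, 15 for halothane 10, 27 for all exposed. With the spike-in level as a block they were 5 for halothane 10, 1 for isoflurane 5, 3 for isoflurane 10. On the low spike-in arrays only they were 0 for halothane 5 and halothane 10 vs 5, 1 for halothane 10, isoflurane 5, all exposed and isoflurane 10 vs 5, 4 for isoflurane 10. On the high spike-in arrays only, with 1 array per exposed group assumed to vary like the controls, they were 48 for halothane 5 and halothane 10, 22 for isoflurane 5, 18 for isoflurane 10, 47 for all exposed, 53 for agents at 5 exposures, 13 for agents at 10 exposures, 52 for halothane 10 vs 5, 19 for isoflurane 10 vs 5, 30 for the interaction. Other counts stayed within 1.5 times. With 1 array left out they ranged over 1 to 2 for halothane 5, 2 to 6 for halothane 10, 0 to 1 for isoflurane 5, 0 to 5 for isoflurane 10, 0 to 3 for all exposed, 0 to 2 for agents at 5 exposures, 0 to 1 for agents at 10 exposures, 0 to 2 for halothane 10 vs 5, 0 to 2 for isoflurane 10 vs 5, 0 to 1 for the interaction. Arrays with equal replicate numbers deviated together between the agents at 10 exposures and between the isoflurane groups, where the block changed no count of probe sets by over 1.5 times. The same held for halothane 10 with isoflurane 5 and halothane 5 with isoflurane 10, which are not compared directly. This does not show pairs, since replicate 3 alone had a high spike-in level in every exposed group. In the other pairs of groups at least 1 correlation was under 0.1. There Ugt2b35 after 5 halothane exposures had an adjusted p of 0.24 under the replicate block, with 0.971 between agents at 5 exposures and 0.699 between halothane 10 and 5.

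The counts of called lists were 0 for halothane 5, 8 for halothane 10, 0 for isoflurane 5, 4 for isoflurane 10, 7 for all exposed, 2 for agents at 5 exposures, 4 for agents at 10 exposures, 4 for halothane 10 vs 5, 1 for isoflurane 10 vs 5, 1 for the interaction. With quantile normalization they were 3 for all exposed, 1 for agents at 5 exposures, 0 for isoflurane 10 vs 5. With median centring they were 2 for all exposed. Without controls 10 to 12 they were 1 for halothane 5 and agents at 5 exposures. With the replicate block, on fewer controls, they were 1 for halothane 5, 5 for halothane 10, 2 for isoflurane 5 and isoflurane 10 vs 5, 0 for isoflurane 10 and all exposed. With the spike-in level as a block they were 1 for isoflurane 5, 2 for isoflurane 10 vs 5. On the low spike-in arrays only they were 3 for all exposed and isoflurane 10 vs 5, 0 for agents at 5 exposures and the interaction. With an estimated correlation they were 0 for halothane 10, isoflurane 10, all exposed, agents at 5 exposures, agents at 10 exposures, halothane 10 vs 5, isoflurane 10 vs 5 and the interaction. By fry, directional, they were 4 for halothane 10, 0 for isoflurane 10, all exposed, agents at 5 exposures, agents at 10 exposures, halothane 10 vs 5, isoflurane 10 vs 5 and the interaction. By fry, mixed, they were 1 for halothane 10 and isoflurane 10, 0 for all exposed, agents at 5 exposures, agents at 10 exposures, halothane 10 vs 5, isoflurane 10 vs 5 and the interaction. With the mean over all probe sets of a gene they were 1 for isoflurane 5, isoflurane 10 and agents at 5 exposures, 0 for all exposed, 2 for isoflurane 10 vs 5. With 1 array left out they ranged over 0 to 2 for halothane 5, 5 to 10 for halothane 10, 0 to 2 for isoflurane 5, 1 to 5 for isoflurane 10, 0 to 8 for all exposed, 0 to 3 for agents at 5 exposures, 0 to 6 for agents at 10 exposures, 0 to 6 for halothane 10 vs 5, 0 to 4 for isoflurane 10 vs 5, 0 to 2 for the interaction.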

Other observations

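All tests here were fixed before the data were examined, except the choice of Alas1 and Il33, named after their values were seen. Genes of inhibitory and excitatory transmission were not called in any comparison by camera, the lowest adjusted p being 0.425 for GABA receptors and synthesis, 0.329 for glutamate receptors and transport, 0.935 for potassium channels, 0.152 for sodium and calcium channels and 0.328 for synaptic vesicle genes. The same held for xenobiotic metabolism (0.192), antioxidant defence (0.842), the unfolded protein response (0.0969), the circadian clock (0.469), hypoxia and glycolysis (0.196), oxidative phosphorylation (0.0671), cytokines and inflammation (0.339), amyloid precursor and tau genes (0.633) and neuropeptides (0.0772). Among markers, those of neurons (0.42), astrocytes (0.178), microglia and macrophages (0.259), endothelium and pericytes (0.0969), pituitary (0.0671) and brain regions (0.156) were not called. Of the sex-linked list 0 genes were measured.

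After 10 halothane exposures Alas1, the first enzyme of haem synthesis, had a log2 fold change of 0.81 and the cytokine gene Il33 of 1.01, each with limma's adjusted p of 0.0902. A second Alas1 probe set was at 0.029.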
